A study of Mus musculus with 2 samples.

How the data were processed

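RNA of single cells was measured in 2 libraries of sorted mouse bone marrow cells, made with the 10x Chromium Single-Cell 3' v2 chemistry. Per the labels, the authors processed the reads with Cell Ranger 2.1.1 and named the builds mm10 and GRCm38.p4. The deposited values were raw UMI counts per gene and cell barcode, with no normalization, and a check of the values found whole numbers from 0 with totals that differed between barcodes. How barcodes had been called as cells was not stated. The tables gave Ensembl identifiers for 27998 genes, of which 27645 matched a symbol in GENCODE release M21 on GRCm38. Old symbols were matched to current ones, as Cyr61 to Ccn1, Ctgf to Ccn2, Wisp1 to Ccn4 and Wisp2 to Ccn5. Of 476 genes in the lists, 474 were in the tables, and Flt3l and Cebpd were not. The 2 libraries shared 4 barcode sequences, and cells were kept apart by library.

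Cells with at least 500 genes detected and under 10% of their UMIs from mitochondrial genes were kept. This left out 6 and 3 barcodes with fewer genes and 43 and 193 with more mitochondrial UMIs in libraries 1 and 2. Scrublet, run per library in scanpy 1.11.5, called 2 and 7 doublets, or 0.207% and 0.409% of the cells tested, and these were left out. Few doublets were called, and joined droplets, of 1 cell type or of several, may remain. UMI counts were scaled to 10000 per cell and log-transformed after adding 1. The 2000 most variable genes were chosen per library and merged, without any gene of the lists and without mitochondrial, ribosomal protein, haemoglobin and immunoglobulin genes. Cells of both libraries were clustered together, with no batch integration, from 30 principal components, 15 neighbours and the Leiden method of igraph 0.11.9 at resolution 1 with seed 0. The scripts ran in Python 3.11.15 (NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, statsmodels 0.14.6, matplotlib 3.10.9).

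Clusters were named from 20 marker sets, fixed beforehand, by thresholds set after the clusters and their marker levels had been seen. A marker counted when at least 0.15 of the cluster's cells held a UMI of it and its level reached 0.25 of that of the highest cluster, and a name needed 3 markers. Endothelial clusters were called sinusoidal-like where Stab2 reached 0.5 of its highest level, a threshold also set after the data were seen. It kept 1 cluster, with 15.0% of the cells of library 1 and 1.23% of library 2, out of that class. A first look at the clusters listed markers with another rule, at least 1.5 times the level of all other cells, and no results were computed under it. The 10 genes with the largest fold against all other cells were also read, and on them 1 cluster that met the osteolineage rule and led with Cytl1, Mmp13 and Spp1 was left without a name of its own, though it stayed in the other mesenchymal-like class. The design had named the third comparison arterial-like against sinusoidal-like. The first of these classes is called Ly6c1-high here for the reason given in the results.

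UMI counts were summed per library and class, for classes with at least 20 cells in each library. The first fit held 6 sums of 3 classes, with 2 residual degrees of freedom, and the second 14 sums of 7 classes, with 6. Both used edgeR 4.0.16 in R 4.3.3 with TMM factors, its filter on low counts, the library as a block and the quasi-likelihood test, with Benjamini-Hochberg adjustment at 0.05 over all tested genes. The common biological coefficient of variation was 0.206 and 0.218. Genes used to cluster were tested but not counted, since the clusters had been drawn from them, and genes correlated with them may still pass more readily than in classes fixed from outside. The 22 gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and again with an estimated one, and with fry, which asks whether a list's genes move on balance 1 way (prior count 2, Benjamini-Hochberg over the lists of a comparison). Members were also counted when adjusted over the list alone.

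The named genes of a comparison were Cxcl12, Il7, Kitl, Vcam1, Nid1 and Enpep always. From each list came the 2 members with the largest change in each direction that passed, kept their sign in both libraries and reached a mean of 50 CPM in the higher class, and from genes in no list, not used to cluster and no markers, the 5 largest in each direction. This gave 72, 79 and 43 genes, of which the text names part, the larger changes first. The lists, marker sets, clustering settings, tests, comparisons and this rule were fixed before the data were examined. No cell was assigned to a sort gate.

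Where a class held 0 UMIs of a gene, the fold was computed against a floor of 3 counts over the class in both libraries and written as at least that fold. Where it held 1 to 3, the ratio is given with an exact 95% counting interval. Both divide UMIs by class totals scaled with the TMM factors. Both also pool the 2 libraries without the block, so they are not bounds within 1 library. Shares have exact Clopper-Pearson 95% intervals, and a share of 0 has the limit that 3 counts allow. Sums held 655250 and 125413 UMIs for reticular cells of libraries 1 and 2, 1523453 and 12845887 for other mesenchymal-like cells, and 579980 and 410136 for endothelial-like cells. Co-detection was set against independence within 5 strata of UMIs per cell in each library.

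The tests were tested on simulated data with the same depths and 200 changed genes. In the 3 comparisons in turn, 16.1%, 3.23% and 8.62% of 2-fold changes and 63.5%, 60.3% and 53.3% of 4-fold changes were called. Of 16-fold changes, 96.8%, 88.7% and 85.5% were called, along with 13, 5 and 6 unchanged genes. These shares hold for the simulated data and may not hold for real genes whose level within a class differs between libraries. Cxcl12 and Kitl were such genes in other mesenchymal-like cells. Their log2 fold changes of 5.73 and 4.83 in reticular against other mesenchymal-like cells did not pass.

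Alternatives were DESeq2 1.42.0 size factors in edgeR, DESeq2's Wald test, no filter on low counts, no replicate block, doublet calls kept, cells with at least 1000 genes and under 5% mitochondrial UMIs, cells thinned to 1500 UMIs, Leiden at resolution 0.5, 1000 variable genes, classes from UMIs of at least 2 markers in place of clusters, and each library left out. The depth for thinning was set after the UMIs per cell were seen. Thinning left out 160 cells of library 1 with fewer UMIs and 0 of library 2. With 1 library no residual degrees of freedom remain, so those folds have no test. They are differences of TMM-normalised log2 CPM with a prior count of 2, while the other folds come from the fits. A gap between them thus holds the change of estimator as well as the library left out. Total UMIs in place of TMM, and the osteolineage-like clusters alone as the other mesenchymal-like class, were chosen after the data were seen, as were stricter filters and 1000 variable genes for class shares.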

Results

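Single-cell RNA profiles were collected from 2 libraries of mouse bone marrow, replicates 1 and 2 of 1 group of C57Bl/6J mice aged 8 weeks. Each library held a mix of sorted cells without CD45, the pan-leukocyte protein. The mix joined stromal cells carrying CD51, CD54 and BP1, named peri-sinusoidal by the study, mesenchymal cells carrying CD51 but neither CD54 nor BP1, and endothelial cells carrying CD31. The genes behind these sort proteins are Itgav for CD51, Icam1 for CD54, Enpep for BP1, Pecam1 for CD31 and Ptprc for CD45. No label ties a cell to its gate, so cells were compared by class, and the classes came from clusters named by marker genes. Library 1 held 1014 barcodes and 3514498 UMIs (unique molecules), with a median of 2367 UMIs per barcode, and library 2 held 1907 barcodes and 16671726 UMIs, with a median of 6656. After filters 964 and 1706 cells remained. The labels do not say whether the 2 libraries came from separate animals, so no p-value is known to measure a spread between animals. With the library as a block, the p-values rest on how the differences between classes varied across these 2 libraries. That variation is pooled over the classes of a fit and may be technical.

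The cells fell into 13 clusters. A reticular stromal-like class (274 cells in library 1 and 33 in library 2) expressed all 11 of its markers, among them the leptin receptor gene Lepr and the adipokine gene Adipoq. The other mesenchymal-like class (226 and 1218 cells) joined osteolineage-like clusters, an Mmp13 and Spp1 cluster left unnamed, and fibroblast-like cells. The endothelial-like class (294 and 119 cells) expressed all 11 endothelial markers and split into a sinusoidal-like cluster with the scavenger receptor gene Stab2 (149 and 98 cells) and a Ly6c1-high cluster (145 and 21 cells). The Ly6c1-high cluster carried 4 of 10 arterial markers, Sox17, Efnb2, Ly6c1 and Glul, but was led by Ramp3, Ly6c1, Aplnr, Col4a1, Emcn and Gpihbp1, several of them capillary genes, so it was not named arterial.

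The 2 libraries differed in their mix of cells. Reticular stromal-like cells made up 28.4% of the kept cells in library 1 (exact Clopper-Pearson 95% interval 25.6 to 31.4) and 1.93% in library 2 (1.34 to 2.71). Other mesenchymal-like cells made up 23.4% (20.8 to 26.2) and 71.4% (69.2 to 73.5), and endothelial-like cells 30.5% (27.6 to 33.5) and 6.98% (5.81 to 8.29). Of the osteolineage-like cells, 144 lay in library 1 and 1146 in library 2. These shares depend on the sort, the mixing and the cell filters, so they were described and not tested. Why they differed between the libraries was not tested either. All intervals and floors given here cover counting error only. Floors and ratios for genes with few UMIs pool the 2 libraries, in which the classes differ in depth, so they do not bound the fold within 1 library.

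**Figure D1:**
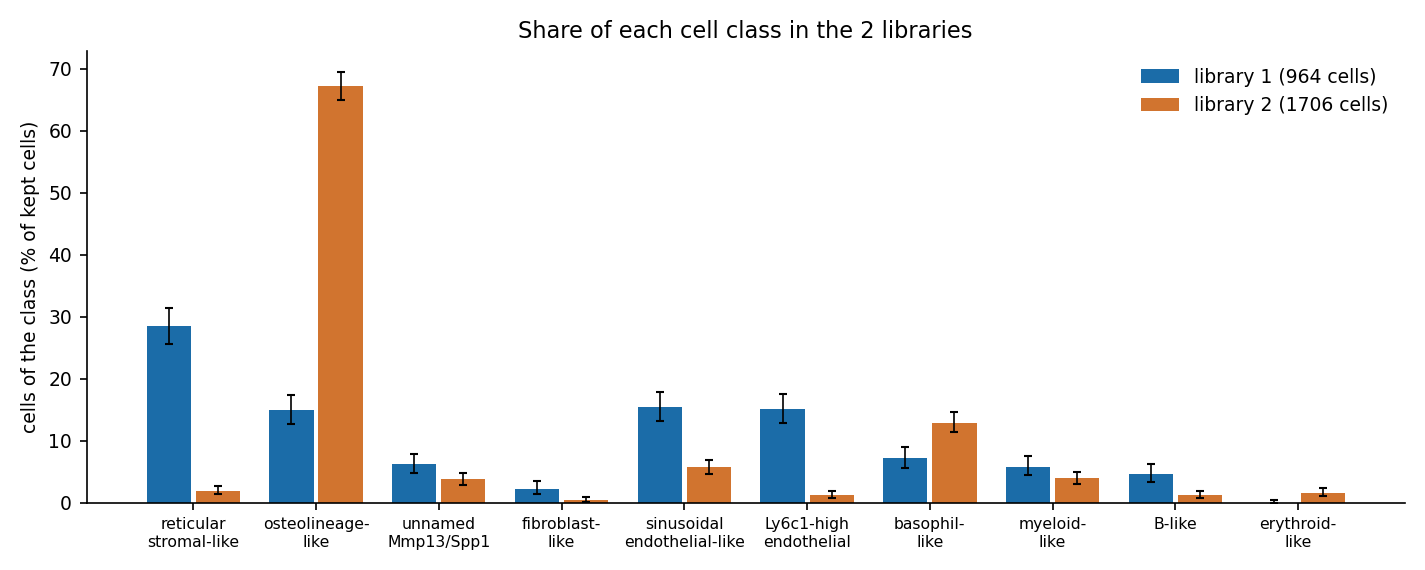
Share of each cell class among the kept cells (vertical axis, percent) in library 1 (blue, 964 cells) and library 2 (orange, 1706 cells), with bars from 0 and exact 95% binomial intervals. Reticular stromal-like cells made up 28.4% of library 1 and 1.93% of library 2.

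The first comparison set reticular stromal-like cells against the other mesenchymal-like cells, since the study's title names the peri-sinusoidal stroma as a niche for haematopoietic stem cells and early B cells. Reticular cells held more transcripts of Il7, the interleukin that early B cells need, of Vcam1, an adhesion molecule that binds integrins of blood cells, and of Bmp4, Csf1, Angpt1 and Il15. The chemokine, antigen presentation and interferon-stimulated lists were higher by camera at the preset correlation, and these calls ended with an estimated one (adjusted p = 0.642, 0.642 and 0.464). The estimated correlation of the interferon-stimulated list, -0.0422, lay under the preset 0.01, so correlation between its genes alone does not account for its lost call. By fry, only the interferon-stimulated list passed in this comparison (adjusted p = 0.0442). The other mesenchymal-like cells held more transcripts of Col1a1, Col1a2 and Sparc and of the galectin gene Lgals1. In the sums, 515 genes were higher and 873 lower in reticular cells (edgeR's quasi-likelihood test with Benjamini-Hochberg over 8004 genes at 0.05, counted over the 6828 that were not used to cluster). Of these, 513 and 873 kept their sign in each of the 2 libraries. Classes drawn from marker UMIs in place of clusters gave 27 higher and 8 lower, of which 11 and 0 were among these calls. They also reversed the direction of 19 of the named genes, among them Sparc, Col1a2, Fn1, Ccn4, Bambi, Cebpa, Tap2 and H2-T23. Other calls ended, among them those of Il7, Bmp4, Col1a1 and Lgals1, so the directions below hold for the clusters. In library 2 the reticular class from marker UMIs held 321 cells with 3349193 UMIs, against 33 cells with 125413 UMIs in the cluster. Most of its UMIs thus came from cells outside the reticular cluster.

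Of the 15 tested niche factors, 8 were higher, 1 was lower and 6 did not pass (9 and 1 when adjusted over the list alone, camera adjusted p = 5.6e-05, adjusted p = 0.660 with an estimated correlation). Throughout, a value after ± is the SE for a log2 fold change and the SD of 2 libraries (n = 2) for a mean, and levels are TMM-normalised CPM, UMI counts scaled to a common library size. Il7 reached 81.5 ± 20.1 CPM in reticular cells and 3.89 ± 4.0 in the others, a log2 fold change of 5.08 ± 0.73 (edgeR's quasi-likelihood test with Benjamini-Hochberg, adjusted p = 0.000728). Without library 1 it was 5.77 and without library 2 it was 2.96. Bmp4, a bone morphogenetic protein gene, was higher by 4.07 ± 0.32 on the log2 scale (4.52 without library 1, 3.33 without library 2), and Lgals1 was lower, with -2.74 ± 0.28. Cxcl12, the chemokine that holds stem cells in the marrow, measured 23658 ± 2476 CPM in reticular cells and 1071 ± 1274 in the others. Its log2 fold change of 5.73 ± 1.66 did not pass (edgeR's quasi-likelihood test with Benjamini-Hochberg, adjusted p = 0.161), with 7.24 without library 1 and 3.49 without library 2. Without TMM, Cxcl12 measured 1348 CPM in library 1 and 100.03 in library 2 in the other mesenchymal-like cells. That was 1.52 (1.31 to 1.78) and 1.64 times (1.28 to 2.13) its level in the basophil-like cells, which should lack it, 885 and 60.9 CPM. Of the 2054 Cxcl12 UMIs of the class in library 1, 1004 lay in the 60 cells of the unnamed Mmp13 and Spp1 cluster, as did all 7 of its Il7 UMIs. The osteolineage-like cells held 786 and 71.3 CPM of Cxcl12 without TMM, in library 1 at 0.889 times the basophil-like level (0.760 to 1.04). Kitl, the stem cell factor gene, measured 779 ± 172 against 50.5 ± 61.6 CPM (log2 4.83 ± 1.20, edgeR's quasi-likelihood test with Benjamini-Hochberg, adjusted p = 0.128), with 6.45 without library 1 and 3.25 without library 2. Both passed DESeq2's Wald test, and over 12 alternatives the adjusted p ran from 4.1e-19 to 0.215 for Cxcl12 and from 3.4e-21 to 0.187 for Kitl.

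The sort gene Icam1 was higher in reticular cells, at 53.2 ± 24.1 against 3.31 ± 0.748 CPM (log2 4.24 ± 0.49, 4.36 without library 1 and 2.66 without library 2). It was the 1 of 4 tested sort genes past the threshold (camera adjusted p = 0.120). The 2 mesenchymal gates had been parted by CD54, the protein of Icam1, so the sort may have set this direction. Enpep, whose protein BP1 marked the peri-sinusoidal gate, gave only 4 and 1 UMIs in the reticular cells of libraries 1 and 2, at 5.69 ± 0.988 against 1.16 ± 1.08 CPM, and did not pass (log2 2.75 ± 1.28, 2.68 without library 1 and 0.80 without library 2, edgeR's quasi-likelihood test with Benjamini-Hochberg, adjusted p = 0.142). Over 11 alternatives, by edgeR or DESeq2's Wald test, the adjusted p of Enpep ran from 0.0365 to 0.9999. Among 22 tested integrin ligands and adhesion molecules, 3 were higher and 5 lower (4 and 6 when adjusted over the list alone, camera adjusted p = 0.889). Vcam1 measured 1639 ± 174 against 85.3 ± 68.1 CPM (log2 4.48 ± 0.64, 5.56 without library 1 and 3.50 without library 2), and the fibronectin gene Fn1 was lower, with -4.14 ± 0.32. Of 14 tested basement membrane genes, 6 were higher and 4 lower, the same counts when adjusted over the list alone (camera adjusted p = 0.349). The laminin gene Lamb1 was higher (2.88 ± 0.33), as was the nidogen gene Nid2 (3.69 ± 0.51, 4.47 without library 1 and 2.26 without library 2), and Sparc was lower (-3.44 ± 0.34). Nid1, the other nidogen gene, measured 135 ± 20.03 against 25.0 ± 29.9 CPM and did not pass (log2 2.99 ± 1.27, 4.76 without library 1 and 1.67 without library 2, edgeR's quasi-likelihood test with Benjamini-Hochberg, adjusted p = 0.276). With the osteolineage-like clusters alone in place of the other mesenchymal-like class, chosen after the data were seen, Nid1 passed with a log2 fold change of 4.50.

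Of 31 tested interstitial matrix genes, 4 were higher and 13 lower in reticular cells (6 and 13 when adjusted over the list alone, camera adjusted p = 0.271). The type I collagen genes Col1a1 (-5.59 ± 0.41) and Col1a2 (-4.51 ± 0.40) fell furthest among the named members, and the collagen gene Col5a3 was higher (3.02 ± 0.65, 4.28 without library 1 and 1.69 without library 2). Antigen presentation genes were higher for 10 of 12 tested members and lower for 0, the same counts when adjusted over the list alone (camera adjusted p = 2.8e-06, adjusted p = 0.642 with an estimated correlation). H2-T23 stood at 2.07 ± 0.27 and the peptide transporter gene Tap2 at 2.24 ± 0.40 (2.66 without library 1, 1.55 without library 2). Interferon-stimulated genes were higher for 13 of 21 members and lower for 0 (16 and 0 when adjusted over the list alone, camera adjusted p = 1.4e-08, adjusted p = 0.464 with an estimated correlation), led by the GTPase gene Iigp1 (4.71 ± 0.39, 5.08 without library 1 and 3.52 without library 2). Chemokine and scavenging receptor genes were higher for 9 of 15 members and lower for 1, the same counts when adjusted over the list alone (camera adjusted p = 0.000873, adjusted p = 0.642 with an estimated correlation). Ccl19, a lymphocyte attractant, was higher by 5.16 ± 0.42 (5.86 without library 1, 4.04 without library 2), and Ccl2, a monocyte attractant, by 5.64 ± 0.48 (5.19 and 4.40). Complement genes gave 3 higher and 2 lower of 12 (4 and 2 when adjusted over the list alone, camera adjusted p = 0.00210, adjusted p = 0.707 with an estimated correlation). The other 7 were not called, and the median log2 fold change of the list was 4.21. C1ra was higher (4.87 ± 0.79, 5.94 without library 1 and 3.56 without library 2), while the regulators Cd59a (-2.72 ± 0.38) and Cfh (-1.41 ± 0.26) were lower. The call of C1ra ended with 1000 variable genes and that of Cfh with total UMIs.

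Of 15 tested adipogenic genes, 4 were higher and 1 lower (4 and 2 when adjusted over the list alone, camera adjusted p = 0.373). The transcription factor gene Cebpa was higher by 3.87 ± 0.44 (4.04 without library 1, 3.16 without library 2) and Pparg by 3.54 ± 0.52 (4.10 and 1.87). Stromal transcription factors were higher for 7 and lower for 2 of 17 (8 and 3 when adjusted over the list alone, camera adjusted p = 0.118), with Runx1 higher (2.48 ± 0.27) and Mef2c lower (-4.10 ± 0.35). The Wnt system split into 7 higher and 5 lower of 18, the same when adjusted over the list alone (camera adjusted p = 0.631). The Wnt modulator gene Sfrp4 was higher (4.23 ± 0.67, 5.01 without library 1 and 3.29 without library 2), and Ccn4 was lower (-4.39 ± 0.33). The Wnt inhibitor gene Dkk1 had 0 UMIs in reticular cells. With both libraries pooled it was at least 22.8-fold lower, by a floor of 3 counts over the class (log2 -6.73 without library 1, -3.74 without library 2). This is no bound within a library, since osteolineage-like cells, with the unnamed cluster included, held 30 Dkk1 UMIs in library 1 and 581 in library 2. The call of Sfrp4 ended with 1000 variable genes, without the replicate block and with the osteolineage-like clusters alone. The BMP and TGF-beta system gave 6 higher and 6 lower of 28 (6 and 7 when adjusted over the list alone, camera adjusted p = 0.631), with the BMP antagonist gene Bambi lower (-3.61 ± 0.30). The Notch system gave 5 higher and 0 lower of 14, the same when adjusted over the list alone (camera adjusted p = 0.118). The insulin-like growth factor system gave 1 higher and 1 lower of 9, the same when adjusted over the list alone (camera adjusted p = 0.0294, adjusted p = 0.678 with an estimated correlation). Angiogenic factors gave 5 higher and 6 lower of 21 (8 and 6 when adjusted over the list alone, camera adjusted p = 0.631), with the growth factor gene Fgf7 higher (4.84 ± 0.41, 5.46 without library 1 and 3.45 without library 2) and Nrp2 lower (-2.32 ± 0.26).

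The remaining lists are given as counts over all genes and then adjusted over the list alone. Integrin subunits gave 1 higher and 1 lower of 8 (2 and 1, camera adjusted p = 0.998), published stromal subset markers 2 and 3 of 10 (3 and 3, camera adjusted p = 0.383), and endocytic receptors 1 and 1 of 11 (1 and 1, camera adjusted p = 0.998). Immediate early genes gave 2 higher and 3 lower of 19 (2 and 4, camera adjusted p = 0.631), heat shock genes 2 and 1 of 11 (2 and 1, camera adjusted p = 0.631), and cell cycle genes 0 and 0 of 10 (0 and 0, camera adjusted p = 0.284). The lists of integrin ligands, integrin subunits, Wnt genes, BMP and TGF-beta genes and immediate early genes had a median and a mean log2 fold change of opposite sign. Among genes of no list, the cadherin-like gene Fat3 had 0 UMIs in reticular cells and was at least 36.3-fold lower (log2 -7.29 without library 1, -5.58 without library 2), and the lysosomal phospholipase gene Pla2g15 was higher (3.52 ± 0.43). The balance of the calls depended on the scaling: total UMIs in place of TMM, chosen after the data were seen, raised the median log2 fold change of all genes by 0.934 and gave 2781 genes higher and 278 lower, so every change here is relative to TMM. With a library left out, the log2 CPM fold of 46 of the 72 named genes lay over 1.5 times away from edgeR's. This gap includes the change of estimator. While 0 genes turned direction, all but the 6 always named had been chosen for the same sign in both libraries. Those chosen so could hardly turn, and the count is no test of their direction.

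The second comparison set the reticular stromal-like cells against the endothelial-like cells of the same libraries, sinusoidal-like and Ly6c1-high together. Reticular cells held more transcripts of Il7, of the lymphocyte attractant Ccl19, of the type VI collagen gene Col6a1 and of the transcription factor genes Runx1 and Prrx1. Endothelial cells held more transcripts of the perlecan gene Hspg2, of the fatty acid carriers Fabp4 and Cd36, and of the adhesion molecules Icam2 and Selp. In all, 687 genes were higher and 475 lower in reticular cells (edgeR's quasi-likelihood test with Benjamini-Hochberg, counted over 6828 genes), and 681 and 475 of them kept their sign in each of the 2 libraries.

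Of 15 tested niche factors, 7 were higher and 0 lower (8 and 0 when adjusted over the list alone, camera adjusted p = 2.7e-06, adjusted p = 0.380 with an estimated correlation). Endothelial cells held 1 UMI of Il7 in all, against 69 in reticular cells, a ratio per TMM-scaled total of 91.4 with a counting interval of 15.9 to 3660 (log2 5.17 without library 1, 4.92 without library 2). The angiopoietin gene Angpt1 was higher by 4.69 ± 0.55 (4.73 without library 1, 4.05 without library 2). Cxcl12 measured 430 ± 503 CPM in endothelial cells, and its log2 fold change of 6.94 ± 1.74 did not pass (edgeR's quasi-likelihood test with Benjamini-Hochberg, adjusted p = 0.127), with 8.40 without library 1 and 4.77 without library 2. Kitl measured 35.2 ± 30.3 CPM there (log2 4.88 ± 1.29, edgeR's quasi-likelihood test with Benjamini-Hochberg, adjusted p = 0.139), with 5.51 without library 1 and 3.91 without library 2. Both passed DESeq2's Wald test here too, and the adjusted p over the alternatives ran from 1.6e-28 to 0.168 for Cxcl12 and from 7.6e-23 to 0.179 for Kitl. Vcam1, at 762 ± 3.09 CPM in endothelial cells, did not pass either (log2 1.11 ± 0.55, edgeR's quasi-likelihood test with Benjamini-Hochberg, adjusted p = 0.252). Nid1 measured 265 ± 40.01 CPM (log2 -1.14 ± 1.19, edgeR's quasi-likelihood test with Benjamini-Hochberg, adjusted p = 0.639) and Enpep 17.4 ± 0.365 CPM (log2 -1.80 ± 0.93, edgeR's quasi-likelihood test with Benjamini-Hochberg, adjusted p = 0.191) in endothelial cells. Over 12 alternatives, by edgeR or DESeq2's Wald test, the adjusted p ran from 0.00988 to 0.984 for Vcam1 and from 0.00592 to 0.7075 for Nid1. Of the 4 tested sort genes Itgav alone was higher (2.36 ± 0.35) and 0 were lower (1 and 1 when adjusted over the list alone, camera adjusted p = 0.621). Both mesenchymal gates had selected CD51, the protein of Itgav, so the sort may have set the direction of Itgav.

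Interstitial matrix genes were higher for 14 of 31 members and lower for 2, the same when adjusted over the list alone (camera adjusted p = 4.0e-07, adjusted p = 0.380 with an estimated correlation). The type VI collagen gene Col6a1 was higher by 6.13 ± 0.82 (7.88 without library 1, 4.86 without library 2). Stromal transcription factors were higher for 12 of 17 and lower for 2, the same when adjusted over the list alone (camera adjusted p = 2.1e-05, adjusted p = 0.380 with an estimated correlation). Runx1 stood at 5.51 ± 0.37, Prrx1 at 4.62 ± 0.44 and the lower Mef2c at -2.73 ± 0.35 (-1.88 without library 1, -3.19 without library 2). Wnt genes were higher for 9 and lower for 2 of 18 (10 and 3 when adjusted over the list alone, camera adjusted p = 0.00518, adjusted p = 0.380 with an estimated correlation). Sfrp1 had 0 UMIs in endothelial cells and was at least 19.0-fold higher in reticular ones (log2 6.62 without library 1, 4.20 without library 2). Complement genes were higher for 5 and lower for 1 of 12 (7 and 1 when adjusted over the list alone, camera adjusted p = 9.8e-05, adjusted p = 0.380 with an estimated correlation), among them C6, a gene of the membrane attack complex, with a ratio of 53.0 (17.7 to 260, log2 5.98 without library 1 and 4.50 without library 2) and a call that ended without the replicate block. Antigen presentation genes were higher for 5 and lower for 0 of 12, the same when adjusted over the list alone (camera adjusted p = 0.00316, adjusted p = 0.380 with an estimated correlation), with the lipid-presenting gene Cd1d1 at 2.74 ± 0.29.

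Basement membrane genes went the other way, with 0 higher and 5 lower of 14 (0 and 6 when adjusted over the list alone, camera adjusted p = 0.0131, adjusted p = 0.380 with an estimated correlation). Hspg2 was lower in reticular cells (-2.16 ± 0.32), as was Col18a1 (-3.28 ± 0.52, -2.26 without library 1 and -3.06 without library 2). The call of Col18a1 ended without the replicate block. It gave 88 and 16 UMIs in Ly6c1-high, 2 and 1 in sinusoidal-like and 10 and 1 in reticular cells of libraries 1 and 2. Its lower level in reticular cells thus rests on the Ly6c1-high cells. All 11 tested endocytic receptor genes passed, 3 higher and 8 lower, the same when adjusted over the list alone (camera adjusted p = 0.0371, adjusted p = 0.380 with an estimated correlation). The mannose receptor gene Mrc1 (-4.63 ± 0.60, -3.87 without library 1 and -4.39 without library 2) and Cd36 (-4.50 ± 0.40, -3.88 and -4.31) were lower, and Lrp1 was higher (4.19 ± 0.38, 4.87 and 3.48). Cell cycle genes were lower for 4 and higher for 0 of 10 (8 and 0 when adjusted over the list alone, camera adjusted p = 0.00151, adjusted p = 0.380 with an estimated correlation), with the tubulin regulator Stmn1 at -1.73 ± 0.32. Adhesion genes split into 5 higher and 5 lower of 22 (6 and 5 when adjusted over the list alone, camera adjusted p = 0.468). The cadherin gene Cdh2 was higher (4.56 ± 0.36, 3.87 without library 1 and 4.84 without library 2), Icam2 was lower (-4.94 ± 0.39), and Selp, the P-selectin gene, was lower with a ratio of 38.5 (10.4 to 322, log2 -7.33 without library 1 and -3.64 without library 2). Chemokine and scavenging receptor genes gave 6 higher and 1 lower of 15, the same when adjusted over the list alone (camera adjusted p = 0.0934). Ccl19 had a ratio of 408 (72.7 to 16160, log2 8.54 without library 1 and 6.52 without library 2), the scavenging receptor gene Ackr4 was higher (5.77 ± 0.37), and Ackr1 was lower (-5.04 ± 0.41).

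The other lists of this comparison are again counted over all genes and then adjusted over the list alone. Adipogenic genes gave 3 higher and 6 lower of 15 (3 and 6, camera adjusted p = 0.307), with Fabp4 at -4.71 ± 0.34. The BMP and TGF-beta system gave 9 and 8 of 28 (9 and 9, camera adjusted p = 0.339), with Id1 at -3.31 ± 0.32, and the Notch system 5 and 7 of 14 (5 and 7, camera adjusted p = 0.624). Angiogenic factors gave 9 and 7 of 21 (9 and 7, camera adjusted p = 0.673), with Fgf7 at a ratio of 81.7 (27.5 to 400, log2 6.90 without library 1 and 5.10 without library 2). Stromal subset markers gave 2 and 5 of 10 (3 and 6, camera adjusted p = 0.109), with Pdgfra at 3.89 ± 0.38 and Mcam, with 0 UMIs in reticular cells, at least 48.6-fold lower (log2 -7.04 without library 1, -6.41 without library 2). Integrin subunits gave 2 and 2 of 8 (2 and 2, camera adjusted p = 0.9996), insulin-like growth factor genes 0 and 1 of 9 (0 and 1, camera adjusted p = 0.289), and immediate early genes 3 and 2 of 19 (3 and 2, camera adjusted p = 0.624). Heat shock genes gave 1 and 2 of 11 (2 and 2, camera adjusted p = 0.9996) and interferon-stimulated genes 2 and 1 of 21 (2 and 1, camera adjusted p = 0.630). The angiogenic and heat shock lists had a median and a mean of opposite sign. DESeq2's Wald test gave 462 higher and 254 lower, the fit without the replicate block 437 and 236, and classes from marker UMIs 42 and 32, which ended the calls of Hspg2, Runx1 and Prrx1 among others. By fry, 7 lists passed: niche factors, stromal transcription factors, Wnt genes, chemokines and cell cycle genes (adjusted p = 0.0421), and interstitial matrix and subset markers (adjusted p = 0.0446). Basement membrane (adjusted p = 0.0711), complement, antigen presentation and endocytic receptors (adjusted p = 0.05002) did not pass it. With a library left out, the log2 CPM fold of 50 of the 79 named genes lay over 1.5 times away from edgeR's. This gap includes the change of estimator. Again 0 genes turned direction, but all except the 6 always named had been chosen for the same sign in both libraries and could hardly turn.

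**Figure D2:**
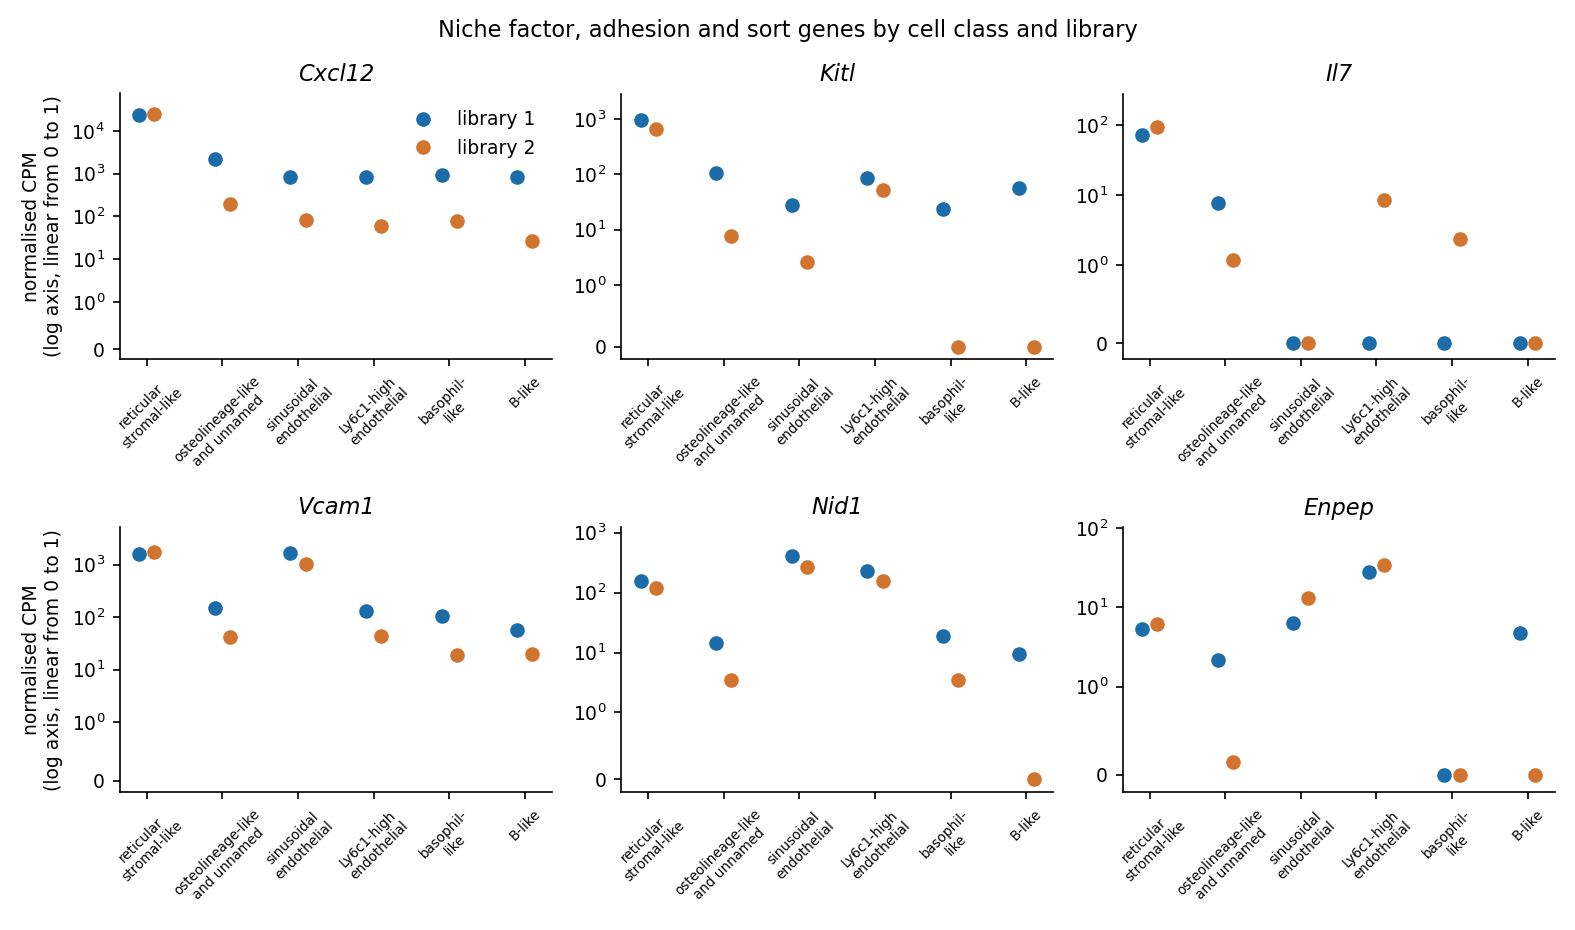
Levels of 6 genes (vertical axes, TMM-normalised CPM, log scale and linear from 0 to 1) in 6 cell classes of library 1 (blue) and library 2 (orange). Cxcl12 lay highest in reticular stromal-like cells of both libraries, while its level in every other class shown was higher in library 1 than in library 2.

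The third comparison set the Ly6c1-high endothelial cluster against the sinusoidal-like cluster. The Ly6c1-high cells held more transcripts of basement membrane genes, a list whose call held with an estimated correlation, among them Col18a1, Col15a1 and Nid2, and of the growth factor gene Ptn. The sinusoidal-like cells held more of the atypical chemokine receptor gene Ackr1, of Fabp4, of the mannose receptor gene Mrc1, and of Vcam1 and Selp, which bind blood cells. In all, 29 genes were higher and 43 lower in the Ly6c1-high cells (edgeR's quasi-likelihood test with Benjamini-Hochberg, counted over 5692 of 6949 genes), and 28 and 43 of them kept their sign in each of the 2 libraries. Without the replicate block 4 were higher and 10 lower, with DESeq2's Wald test 17 and 29, and with total UMIs in place of TMM, which moved the median log2 fold change by 0.124, 34 and 30.

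Of 14 tested basement membrane genes, 5 were higher and 0 lower (8 and 1 when adjusted over the list alone, camera adjusted p = 4.2e-07, adjusted p = 0.0282 with an estimated correlation). Col18a1 had 3 UMIs in sinusoidal-like cells, a ratio of 47.5 (15.8 to 234, log2 5.18 without library 1 and 4.38 without library 2), and Col15a1 also had 3, a ratio of 32.4 (10.7 to 161, log2 3.07 without library 1 and 4.45 without library 2). Nid2 was higher by 3.34 ± 0.62 (4.48 without library 1, 2.25 without library 2). Nid1 measured 192 ± 52.5 against 341 ± 103 CPM and did not pass (log2 -0.88 ± 0.35, edgeR's quasi-likelihood test with Benjamini-Hochberg, adjusted p = 0.284). Adipogenic genes were higher for 0 and lower for 4 of 13, the same when adjusted over the list alone (camera adjusted p = 0.00121, adjusted p = 0.160 with an estimated correlation). Fabp4 measured 1162 ± 328 against 10932 ± 506 CPM (log2 -3.26 ± 0.32), and Cfd, the adipsin gene, with 0 UMIs in the Ly6c1-high cells, was at least 17.8-fold lower (log2 -6.07 without library 1, -4.72 without library 2). Antigen presentation genes were higher for 0 and lower for 2 of 16 (0 and 3 when adjusted over the list alone, camera adjusted p = 0.00595, adjusted p = 0.595 with an estimated correlation), with H2-K1 at -1.24 ± 0.32. Endocytic receptors were higher for 0 and lower for 3 of 11 (0 and 4 when adjusted over the list alone, camera adjusted p = 0.194), with Mrc1 at -3.83 ± 0.45 (-5.20 without library 1, -3.20 without library 2).

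Among 22 adhesion genes, 3 were higher and 2 lower (4 and 8 when adjusted over the list alone, camera adjusted p = 0.669). Vcam1 measured 85.8 ± 60.4 against 1327 ± 459 CPM (log2 -4.09 ± 0.74, edgeR's quasi-likelihood test with Benjamini-Hochberg, adjusted p = 0.0189). Its call ended with DESeq2's size factors, with total UMIs and without the replicate block. Selp was lower (-3.70 ± 0.72, -2.37 without library 1 and -3.79 without library 2). Of 14 chemokine and scavenging receptor genes 1 was higher and 1 lower (1 and 2 when adjusted over the list alone, camera adjusted p = 0.669), the lower one Ackr1 at 23.2 ± 20.6 against 1012 ± 513 CPM (log2 -4.94 ± 0.43, -7.04 without library 1 and -3.95 without library 2). Of 20 angiogenic genes 1 was higher and 2 lower, the same when adjusted over the list alone (camera adjusted p = 0.353), with the lipase inhibitor gene Angptl4 at -3.60 ± 0.54 (-4.39 without library 1, -3.10 without library 2). Of 16 niche factors 1 was higher and 0 lower, the same when adjusted over the list alone (camera adjusted p = 0.448). That gene, Ptn, had 1 UMI in sinusoidal-like cells and 106 in the Ly6c1-high cells, a ratio of 145 (25.5 to 5791, log2 6.77 without library 1 and 4.89 without library 2). Its call ended with DESeq2's size factors, with total UMIs and with doublet calls kept. Kitl measured 68.7 ± 24.1 against 15.4 ± 18.1 CPM (log2 2.11 ± 1.63, edgeR's quasi-likelihood test with Benjamini-Hochberg, adjusted p = 0.807), with 3.79 without library 1 and 1.46 without library 2. Cxcl12 measured 454 ± 556 against 450 ± 522 CPM (log2 -0.07 ± 1.24), and Enpep 31.1 ± 4.76 against 9.65 ± 4.77 CPM (log2 1.5 ± 1.08), neither past the threshold. Il7 gave 1 UMI in the Ly6c1-high cells and 0 in the sinusoidal-like ones.

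In the other lists few genes passed, and the counts were the same when adjusted over the list alone unless given. The BMP and TGF-beta system gave 2 higher and 1 lower of 24 (camera adjusted p = 0.919), with Id2, an inhibitor of differentiation, at -1.61 ± 0.36. Interstitial matrix genes gave 1 higher and 2 lower of 30 (2 and 2 over the list alone, camera adjusted p = 0.669), with Col6a3 lower at a ratio of 26.6 (7.11 to 224, log2 -6.22 without library 1 and -3.49 without library 2). Sort genes gave 0 and 1 of 6 (camera adjusted p = 0.753), with Icam1 at -1.77 ± 0.49. Subset markers gave 1 and 0 of 10 (camera adjusted p = 0.194), with Cd200 at 1.41 ± 0.30, and immediate early genes 1 and 0 of 17 (camera adjusted p = 0.906), with the flow-responsive gene Klf2 at 1.33 ± 0.35. Complement genes gave 0 and 1 of 13 (camera adjusted p = 0.194), with Cd55 at -2.93 ± 0.68, and interferon-stimulated genes 0 and 1 of 18 (camera adjusted p = 0.669), with Iigp1 at -1.84 ± 0.43 (-2.57 without library 1, -1.28 without library 2). Of the genes named here and above, Klf2 and Icam1 lost their call under 6 and 7 of 9 alternatives, Cd55 and Iigp1 under 3, and H2-K1, Id2 and Cd200 without the replicate block. Insulin-like growth factor genes gave 0 and 0 of 7 (1 and 2 over the list alone, camera adjusted p = 0.526). Integrin subunits gave 0 and 0 of 8 (camera adjusted p = 0.919) and stromal transcription factors 0 and 0 of 14 (camera adjusted p = 0.448). Wnt genes gave 0 and 0 of 13 (camera adjusted p = 0.753), Notch genes 0 and 0 of 13 (camera adjusted p = 0.612). Heat shock genes gave 0 and 0 of 11 (camera adjusted p = 0.344) and cell cycle genes 0 and 0 of 20 (camera adjusted p = 0.470). The lists of integrin subunits, BMP and TGF-beta genes, Notch genes, immediate early genes and interferon-stimulated genes had a median and a mean of opposite sign. By fry, the basement membrane (adjusted p = 0.00497) and adipogenic lists (adjusted p = 0.00652) passed. The Ly6c1-high sum of library 2 rested on 21 cells and held 340 UMIs of Ccl21a and 34 of Lyve1, genes of lymphatic endothelium, against 0 and 0 in that of library 1. Another endothelial type may therefore sit in this sum, and its cells were not left out. With a library left out, the log2 CPM fold of 28 of the 43 named genes lay over 1.5 times away from edgeR's. This gap includes the change of estimator, and 1 gene, Cxcl12, turned direction. Cxcl12 is 1 of the 6 genes always named, and the others had been chosen for the same sign in both libraries.

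**Figure D3:**
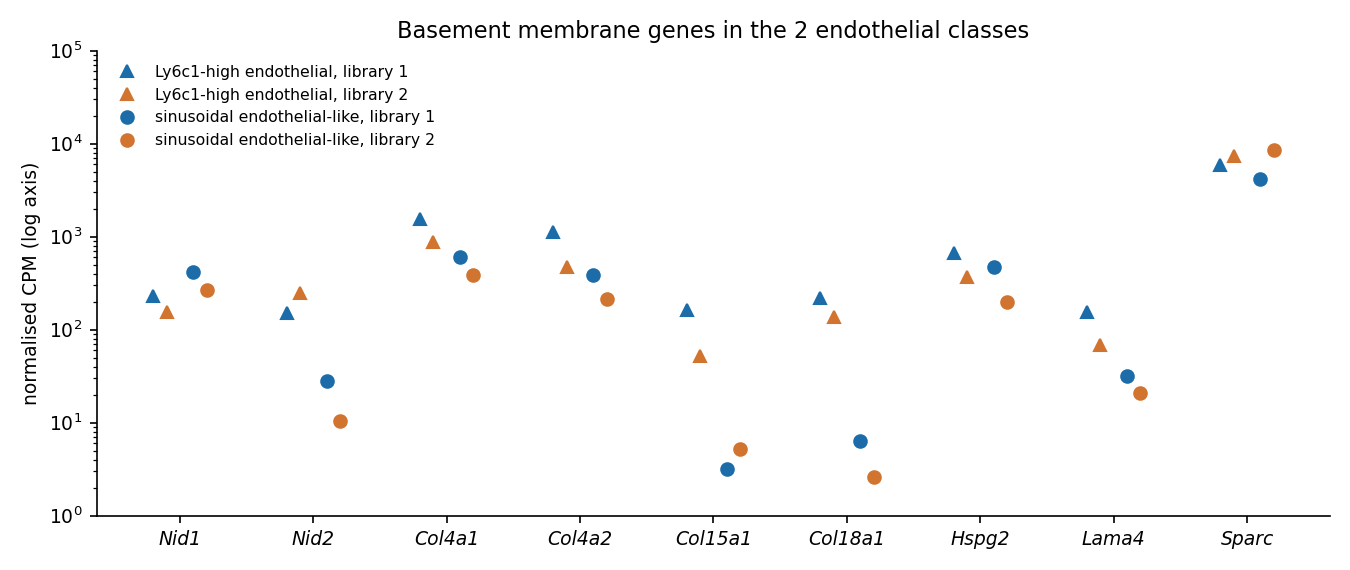
Levels of 9 basement membrane genes (vertical axis, TMM-normalised CPM, log scale) in the Ly6c1-high (triangles) and sinusoidal-like (circles) endothelial cells of library 1 (blue) and library 2 (orange). Nid2, Col15a1 and Col18a1 lay higher in the Ly6c1-high cells of both libraries, and Nid1 lay lower.

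Detection of the niche factors in the same cells was then counted, since the title names 1 niche for stem cells and early B cells. Cxcl12 UMIs were found in 100% of the reticular cells of each library, 274 of 274 and 33 of 33. Kitl UMIs were found in 88.3% and 87.9% of them, and Il7 UMIs in 16.4% (45 cells) and 30.3% (10 cells), at median depths of 2226 and 3399 UMIs. In library 1, 42 reticular cells held both Il7 and Kitl, or 15.3% (11.3 to 20.2), against 14.7% if detection were independent within 5 depth strata. In library 2, 9 cells did, or 27.3% (13.3 to 45.5), against 29.4%. At this depth the observed shares did not part from independence. The share with both cannot exceed that with Il7, 16.4% and 30.3%, which lies inside the interval of each library. A positive link could thus not have been seen, and no conclusion is drawn. Free RNA also gives UMIs, so the shares were set beside those in basophil-like cells, which should lack these genes, at median depths of 2486 and 4456 UMIs. There Cxcl12 was found in 85.5% and 25.9% of cells, Kitl in 5.80% of library 1, and Il7 in 0 of 69 cells of library 1, which allows a share of cells with a UMI of up to 4.35%, and in 0.909% of library 2. Kitl was found in 0 of 220 basophil-like cells of library 2, which allows up to 1.36%. In endothelial-like cells, at median depths of 1780.5 and 3260 UMIs, Kitl was found in 11.2% and 4.20%, and Il7 in 0 of 294 and 1 of 119 cells.

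The 6 genes named in each comparison are protein coding on build GRCm38. Cxcl12 (ENSMUSG00000061353) lies on chromosome 6 from 117168535 to 117181367, and Kitl (ENSMUSG00000019966) on chromosome 10 from 100015630 to 100100416. Il7 (ENSMUSG00000040329), Vcam1 (ENSMUSG00000027962) and Enpep (ENSMUSG00000028024) lie on chromosome 3, from 7569994 to 7613760, from 116109949 to 116129688 and from 129269175 to 129332720. Nid1 (ENSMUSG00000005397) lies on chromosome 13 from 13437551 to 13512269.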

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

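The tests of endothelial-like cells' own Cxcl12, of background in myeloid-like cells, of haemoglobin as shared background, and all 3 tests on basophil-like cells were chosen only after the result was seen. Signals of cells that the sort for CD45-negative, lineage-negative cells would remove appeared above the limit that a count of 0 allows, which is 0.311% of the kept cells in library 1 and 0.176% in library 2. Basophil-like cells, named by Mcpt8, Prss34 and other markers, made up 7.16% of library 1 and 12.9% of library 2. Neutrophil-like myeloid cells made up 5.81% and 3.93%, and B-like cells, named by Cd79a, Cd79b, Cd19, Vpreb3 and Igll1, 4.67% and 1.23%. Erythroid-like cells made up 1.64% of library 2, and 0 were found in library 1. The B-like cluster also carried the dendritic cell markers Siglech and Flt3 and was not stable: 11 cells of library 1 were B-like at resolution 0.5, against 45 here, while the myeloid-like cells rose from 56 to 85. No biological explanation was tested, since both libraries belong to 1 group.

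The basophil-like cells held 43631 and 42532 CPM of Mcpt8, a basophil protease gene, against 570 and 810 in osteolineage-like cells, all without TMM. An absence of Ptprc transcripts, the gene of CD45, was excluded as the account of their passing the gate: Ptprc was 14.5 times its level in osteolineage-like cells in library 1 (6.12 to 38.1) and 27.7 times in library 2 (18.6 to 42.0). Droplets joined with an osteolineage-like cell were excluded too, since Bglap, an abundant osteoblast gene, was at most 1.20 times its level in endothelial-like cells (1.10 to 1.31). Droplets joined with a reticular cell were also excluded, since Cxcl12 was at most 1.13 times its level in osteolineage-like cells (0.959 to 1.32). Low CD45 protein on the surface may be another account and stays open, since proteins were not measured.

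Transcripts of reticular cells also appeared in all other classes, with 885 CPM of Cxcl12 in basophil-like and 1029 in endothelial-like cells of library 1, and 60.9 and 92.7 in library 2, all without TMM. An equal number of background molecules in each droplet was excluded, as the slope of log reticular-marker UMIs on log total UMIs lay above 0.5 by more than 2 SE in 4 of 6 classes of library 1. Background in proportion to a barcode's molecules had the values it needs, with a median slope of 0.807 and 5 of 6 classes within 0.3 of 1, though osteolineage-like cells lay under 1 by more than 2 SE (0.710, SE 0.0464). It was excluded as the whole cause in the neutrophil-like myeloid cells of library 1 (slope 0.513, SE 0.378), which held Cxcl12 at 2.39 times the basophil-like level (2.02 to 2.83), and what raised it there stays open. Whether endothelial-like cells also express Cxcl12 cannot be told apart from this background, since their level was 1.52 times that of basophil-like cells in library 2 (0.993 to 2.30) and 1.16 times in library 1 (0.987 to 1.38).

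Haemoglobin UMIs made up more of all UMIs in reticular stromal-like and sinusoidal-like cells than in osteolineage-like cells. Background in proportion to a barcode's molecules was excluded as the whole cause. The lowest ratio of these shares, for sinusoidal-like cells of library 2, was 3.97 (3.47 to 4.53). This ratio cannot exclude an equal number of background molecules in each droplet, since osteolineage-like cells were deeper. Their median depth in library 2 was 9217.5 UMIs, against 3207.5 in sinusoidal-like and 3399 in reticular cells. Haemoglobin was found in 80.5%, 50% and 72.7% of these cells in turn, and in 33.3%, 16.1% and 32.1% in library 1. Whether a few cells joined with an erythroid cell brought the haemoglobin UMIs cannot be told apart. The top 5% of cells held at least 52.3% of the haemoglobin UMIs in each class and library, but in library 1 this was also so in classes such as Ly6c1-high (68.9%) and neutrophil-like cells (62.1%), and that library held 0 erythroid-like cells.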

How the results depend on the processing

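The alternatives with total UMIs, with the osteolineage-like clusters alone and, for class shares, with stricter filters and 1000 variable genes were chosen after the results were seen, and the others earlier. The depth for thinning and the thresholds that name clusters were also set after the data were seen, and no results were computed under other naming thresholds. Gene counts within 1.5 times those reported came from DESeq2's size factors, no filter on low counts, doublet calls kept, stricter cell filters, resolution 0.5, 1000 variable genes and the osteolineage-like clusters alone, for the comparisons each could be run on. Leiden at resolution 0.5 merged the endothelial clusters, and marker UMIs or the osteolineage-like clusters alone define no endothelial subclasses, so these gave no value for the third comparison. Reticular cells against other mesenchymal-like cells gave 309 higher and 504 lower with DESeq2's Wald test, 245 and 451 with thinned cells, 269 and 450 without the replicate block, 27 and 8 with classes from marker UMIs, and 2781 and 278 with total UMIs. Against endothelial cells they gave 254 lower with the Wald test, 450 higher and 275 lower with thinned cells, 437 and 236 without the block, and 42 and 32 with marker UMIs. The third comparison gave 17 higher with the Wald test, 16 with thinned cells, and 4 higher and 10 lower without the block. Total UMIs differ from TMM by construction in the weight of the osteolineage-like cells' abundant transcripts, and thinning leaves fewer counts, while for the others the cause was not tested.

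With classes from marker UMIs, 394 and 321 cells became reticular and 64 and 779 other mesenchymal-like in libraries 1 and 2, and 19 log2 fold changes of the first comparison reversed: Fn1 0.39, Sparc 0.34, Col1a2 0.26, Scd1 0.22, Cebpa -0.37, Ly6e -0.89, Bmp3 0.077, Bambi 0.090, Dkk1 0.34, Ccn4 0.025, Cd59a 0.38, Cfh 0.52, Tap2 -0.18, H2-T23 -0.047, Junb -0.27, Zfp469 0.084, Zbtb7c 0.086, Sema3d 0.48 and Dock8 -0.44. In the second comparison Fosl2 reversed, at 0.048. The marker rule took no account of a cell's depth. In library 2 its reticular class held 3349193 UMIs, against 125413 in the reticular cluster, so most of them came from cells outside that cluster. Which cells these were was not counted, and the cause of the reversals was not tested further. Cxcl12 in the third comparison, not called, took values of 0.12 with 1000 variable genes, 0.31 with doublet calls kept, 0.060 without the block, 0.27 with stricter filters and 0.040 with total UMIs, where the cause was not tested. Leaving out libraries aside, of 856 recomputed folds of named genes in the first comparison 756 kept direction and side of the threshold, 70 lost their call and 11 gained one. Of 943 in the second 861 kept them, 69 lost and 12 gained, and of 374 in the third 281 kept them, 88 lost and 0 gained.

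With an estimated correlation, camera's adjusted p became 0.660 for niche factors, 0.678 for insulin-like growth factor genes, 0.707 for complement, 0.642 for antigen presentation, 0.642 for chemokines and 0.464 for interferon-stimulated genes in the first comparison. It became 0.380 for the 9 lists called in the second, and 0.160 for adipogenic genes and 0.595 for antigen presentation in the third. Only the basement membrane list of the third kept its call, at 0.0282. Interferon-stimulated genes in the first comparison, and Wnt and cell cycle genes in the second, had estimated correlations of -0.0422, -0.0113 and -0.0816. These lie under the preset 0.01, so correlation alone does not account for their lost calls. The other lists that lost calls lay above it, some only just, with 0.0130 for stromal transcription factors in the second and 0.0166 for chemokines in the first. For the stromal transcription factors camera's adjusted p still rose from 2.1e-05 to 0.380. Correlation is thus not shown to account for the other losses either. The first 2 comparisons had 2 residual degrees of freedom and the third 6, so the kept call is not set above theirs. The cause was not tested further. With cells thinned to 1500 UMIs, both Il7 and Kitl were found in 7.63% of the reticular cells of library 1 and 15.2% of library 2. Il7 and Cxcl12 were found in 10.2% and 18.2%, and Kitl and Cxcl12 in 74.2% and 66.7%, since thinning leaves fewer UMIs. Shares of the reticular, other mesenchymal-like and endothelial-like classes stayed inside their intervals with doublet calls kept, with resolution 0.5 and with 1000 variable genes. Stricter cell filters moved shares outside, to 33.4% reticular and 25.5% endothelial-like in library 1 and to 62.1% other mesenchymal-like, 2.75% reticular, 9.51% endothelial-like and 25.7% other cells in library 2, where the cause was not tested. The B-like and myeloid-like clusters did not keep their cells. With doublet calls kept, 11 and 14 cells were B-like and 90 and 74 myeloid-like in libraries 1 and 2, and with resolution 0.5 these were 11 and 14, and 85 and 74. The erythroid-like cluster was not found apart at resolution 0.5. The cause was not tested.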

Other observations

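The classes outside the comparisons carried list genes of their own, and all values here were read after the data were seen. Basophil-like cells held 311 and 1987 CPM of the cytokine gene Il6 in libraries 1 and 2, against 3.29 and 22.2 in osteolineage-like cells with the unnamed cluster included. They also held 2123 and 11177 CPM of Ccl4, a chemokine gene, against 50.4 and 363, and 173 and 207 CPM of the hepatocyte growth factor gene Hgf, against 0 and 2.71. Ifitm1, an interferon-induced gene, measured 1366 and 2070 CPM in basophil-like cells and 218 and 169 in reticular cells. The B-like cluster also carried the dendritic cell markers Siglech (24 and 21 UMIs) and Flt3, and Cd79a was found in 37.9% of its cells, so it may join more than 1 cell type. Its cells held 1058 and 632 CPM of Cd74 and 128 and 226 CPM of H2-Aa, both genes of antigen presentation by MHC class II, against 3.96 and 6.24 CPM of Cd74 in reticular cells.

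The unnamed Mmp13 and Spp1 cluster, with 60 cells in library 1 and 64 in library 2, held more Cxcl12 than basophil-like cells, by 5.61 times in library 1 (4.80 to 6.58) and 15.1 times in library 2 (11.6 to 19.9). It gave 7 and 3 UMIs of Il7 and 46 and 4 UMIs of Kitl. Among the classes, Enpep lay highest in Ly6c1-high endothelial cells, 5.66 times its level in reticular cells in library 1 (1.68 to 24.4) and 6.39 times in library 2 (0.633 to 315), where 4 UMIs stood against 1. The osteolineage-like clusters parted by library, with 138 of the 144 such cells of library 1 in a cluster that held 4 cells of library 2.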
